A study of Mus musculus with 6 samples.

How the data were processed

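Total RNA from mouse embryonic stem cells was labelled with biotin and hybridised to Affymetrix MG U74Av2 arrays, 1 colour and 1 array per sample. The labels give 6 samples, 3 wild type and 3 HDAC1 knockout, and number each group from 1 to 3 as biological replicates. The series' design text says that both kinds of cell came from 1 litter. No label says whether the replicates of a genotype came from separate lines or cultures, so p-values measure the spread between these samples, which may be partly technical. The culture protocol in the labels allows either LIF on gelatin or feeder layers without LIF and does not say which sample had which.

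The deposited values were linear signal intensity per probe set, made by the authors with MAS5, per the submitters' processing notes. The version, the background settings and the detection calls are not given in the sources used here. The mean of each array's signals, after trimming 2% of probe sets at each end, was 500.3 on all 6 arrays, so the deposited intensities had been scaled to a common level. By a rule set before the data were examined (trimmed means within 5% of one another), they were used as deposited. Such global scaling makes the arrays' overall levels equal, so a change of all transcripts in one direction cannot be seen in these values. The experiment headers of the 6 arrays were used only to look for scan or fluidics batches. They were identical, so they cannot show whether such batches existed.

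The table held 12488 probe sets, of which 66 were Affymetrix controls and 12422 were tested. Gene names came from the platform annotation, updated by gene identifier through a RefSeq table of the assembly GRCm38.p6. Of the tested probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had none, and 10817 of the first kind matched the RefSeq table by identifier. No gene was named from a probe set with several symbols. For tests per gene, the probe set with the highest mean signal over all 6 arrays stood for its gene, which gave 8251 genes. Chromosomes were taken from the same RefSeq table, and its start positions were used only to order genes along a chromosome.

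Values were analysed as log2(signal + 16) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), as HDAC1 knockout minus wild type over all 6 arrays without covariates. P-values were adjusted with Benjamini-Hochberg over the 12422 probe sets, and a probe set was called at an adjusted p under 0.05. Fold changes are on the log2(signal + 16) scale, which understates changes of dim probe sets. Errors on signals are SDs over 3 arrays, and errors on log2 differences are limma's standard errors. Adjusted p-values are limma's unless another test is named. The number of arrays limits the precision.

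As no detection calls were used, a background level was set after the values had been seen, at the 95th percentile of 19 control probe sets for bacterial and yeast transcripts, a signal of 116.4. Where all 3 arrays of 1 group, or the mean of the group, lay at or under this level, the fold is given as a lower bound ("at least"), with each array under it set to the background level and the other group as measured. Where both groups did, no fold is given. A mean at or under the background level was found for 39.2% of tested probe sets.

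Gene lists (29) and marker lists of other possible sources of RNA (4) were fixed before the data were examined. Each list was tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of its kind that had at least 5 measured genes. Camera with an estimated correlation and fry were run as alternatives. Members were counted both by the adjustment over all probe sets and adjusted over the list alone. Named genes are, by a rule fixed beforehand, the 15 largest rises and 15 largest falls among called genes whose groups did not overlap, Hdac1, Hdac2, Hdac3, Cdkn1a and Cdkn1b, and up to 4 members with the smallest p of each list described. Other genes are said to have been chosen after their values were seen. RNA quality was followed by the 3' to 5' signal ratio of the Gapdh and beta-actin control probe sets, with an exact two-sided permutation test.

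The alternatives set beforehand were pseudocounts of 1 and 64, quantile normalization, median centring of the log2 values, leaving out the 25% or 50% of probe sets with the lowest mean signal, eBayes without a trend or with robust estimation, array weights, the replicate number as a block, leaving out each array, other thresholds, genes in place of probe sets, and other list tests. A fit without X-linked and Y-linked genes was added after the data had been seen. The scripts were tested on simulated data made from the real means of the 12422 probe sets in this comparison. The noise was normal, with the SD that eBayes with a trend gave each probe set. Of probe sets above background changed 2-fold, 64% were called in the right direction, and of those changed 4-fold, 95%. With 200 probe sets changed, 9 unchanged probe sets were called, and 0 were called when nothing was changed. A list shifted by 0.4 on the log2 scale was the 1 list called. The simulated noise was independent between probe sets, so this does not test list calls where genes are correlated. It also followed the variance model of the main fit, so the simulation does not test that model.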

Results

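Transcript levels were measured on 1-colour arrays in wild-type and HDAC1 knockout mouse embryonic stem cells, pluripotent cells derived from early embryos, with 3 arrays per genotype. HDAC1 is a class I histone deacetylase that acts in several corepressor complexes. The comparison asks which transcripts differ between the genotypes. The sex chromosomes of the samples are not given, and no sample separates them from the loss of HDAC1. Median signals of the arrays lay between 186.6 and 207.5. Among the 7548 probe sets above the background level, the correlation of log2 signals across probe sets was 0.939 to 0.958 within a genotype and 0.920 to 0.934 between genotypes.

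Hdac1 itself fell in all 3 knockout arrays. Its signal was 2310.3 ± 104.7 (SD, n = 3) in wild-type cells and 141.8 ± 48.0 (SD, n = 3) in knockout cells, 15.2-fold lower, and the 3 knockout values of 118.3, 110.1 and 197.1 lay close to the background level of 116.4. The log2 difference was -3.92 ± 0.19 (SE), with an adjusted p of 2.32e-06 by limma. Hdac2, the closest paralog, had a signal of 1266.4 ± 179.2 in wild-type and 1723.6 ± 102.4 in knockout cells, a 1.36-fold difference with no overlap between the groups that missed the threshold (adjusted p = 0.0636). Over the other settings its adjusted p ran from 0.0306 with median centring to 0.333. Hdac3 had a log2 difference of -0.12 ± 0.29 (adjusted p = 0.914), with 1 knockout array setting its sign, as its log2 difference was 0.24 without HDAC1 knockout replicate 2. Of the 6 histone deacetylase genes measured, 1 rose, 1 fell and 4 had no call, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.784). The gene that rose was Hdac6 on the X chromosome, 1.43-fold higher. None of the 17 measured HDAC1 corepressor complex subunits was called by limma, against 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.46). At an unadjusted p under 0.05 there were 7 of the 17 (41.2%), in both directions, and 1912 of all tested probe sets (15.4%). The 17 are the brightest probe set of each gene, while the second share includes the dim probe sets. Shares of the gene lists ran from 8.3% (histone genes) to 64.3% (pluripotency genes), so 41.2% is not particular to these subunits.

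**Figure D1:**
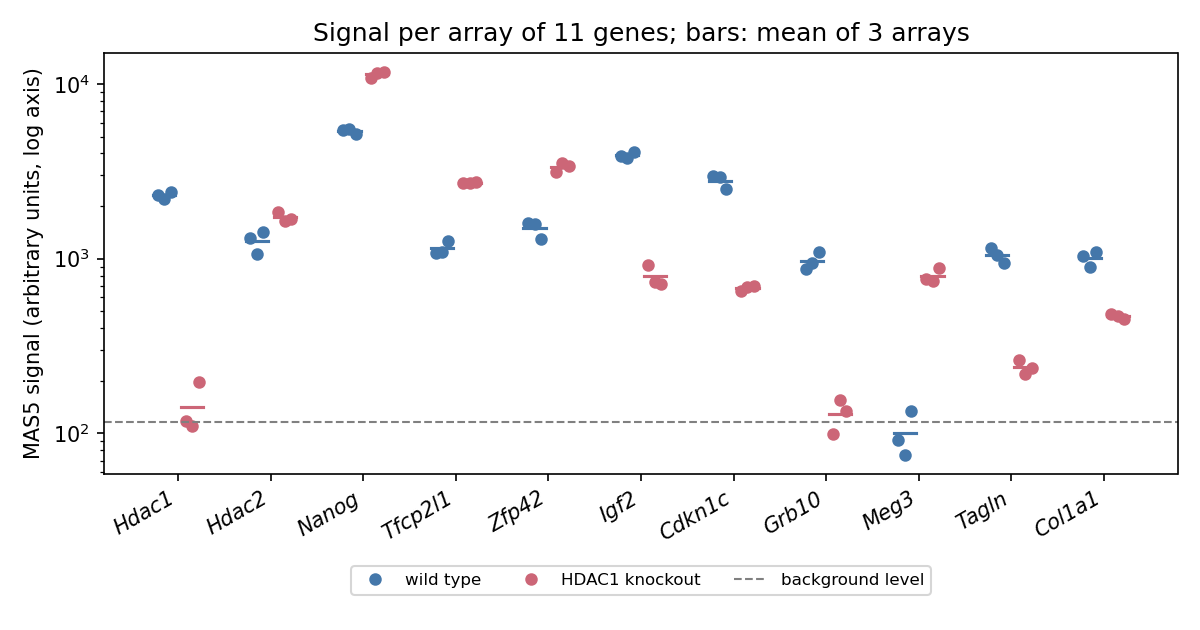
MAS5 signal on each array (log axis, arbitrary units) of 11 genes in wild-type (blue) and HDAC1 knockout (red) cells, with bars at the mean of 3 arrays and a dashed line at the background level of 116.4. Hdac1 fell from a mean of 2310.3 to 141.8, while Nanog rose from 5394.3 to 11376.4 and Igf2 fell from 3912.9 to 794.5.

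Over all probe sets, 279 were higher and 203 lower in knockout cells, 3.88% of the 12422 tested, and 92 and 66 of them differed by at least 2-fold. Per gene, 223 were higher and 155 lower of 8251. The 2 groups of arrays did not overlap for 20.6% of probe sets, where chance gives 10%, and for all 482 called. The counts depended on the variance model, with 82 higher and 50 lower without a trend, and on scaling, since centring on the median moved the share of higher calls from 57.9% to 72.7% (344 higher, 129 lower). Leaving out HDAC1 knockout replicate 1, 2 or 3 gave 183, 150 and 157 higher and 121, 98 and 112 lower, and leaving out wild type replicate 1 or 2 gave 110 and 116 lower. Without X-linked and Y-linked genes, a fit added after the data had been seen, 210 probe sets were higher and 176 lower. Of 112 called genes with several probe sets, 35 had another probe set of opposite sign, and for 1 gene that probe set was itself called.

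A probe set for Meg3, an imprinted long non-coding RNA, rose at least 5.85-fold, from 100.8 ± 30.5 with 2 of 3 arrays at background to 795.5 ± 73.9, while the gene's second probe set had 371.3 ± 151.5 and 343.1 ± 28.4 (log2 difference -0.03, adjusted p = 0.981). Rhox5, a homeobox gene on the X chromosome, rose 3.99-fold from 1166.0 ± 178.9 to 4671.2 ± 315.4. The meiotic cohesin subunit Stag3 was at background in wild-type cells and at least 2.42-fold higher in knockout cells, Pramel6 at least 2.65-fold and the X-linked lymphocyte-regulated gene Xlr4a at least 1.73-fold. Lpar1, a receptor for lysophosphatidic acid, rose at least 2.95-fold, with 2 of 3 wild-type arrays at background, the desmosomal cadherin Dsg2 3.92-fold, Spg21 5.07-fold and the RNA helicase Ddx19b 4.18-fold. The membrane metallopeptidase Mme, the proteoglycan core protein Srgn, the acute-phase protein gene Saa3, Aldh3a1, Clec11a and the hyaluronan synthase Has1 rose from background by at least 1.22-fold (Srgn) to at least 1.99-fold (Aldh3a1), with 1 of 3 knockout arrays of Srgn at background as well. Adjusted p-values of these 15 genes by limma ran from 3.89e-06 for Ddx19b to 0.0232 for Has1. Single arrays left out ended the call of Has1 for 5 of the 6 arrays, Lpar1 and Aldh3a1 for 4, Clec11a for 3, and Srgn and Saa3 for 2, with adjusted p up to 0.126. The second probe set of Dsg2 was not called (adjusted p = 0.0745), and that of Aldh3a1 was at background in both groups. Among probe sets that name no single gene, 1 annotated to 2 genes on chromosome 7 rose from 491.3 to 5179.1, and 1 annotated to 3 genes on the X chromosome rose at least 24.2-fold.

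Among the largest falls after Hdac1, Grb10, an adaptor that restrains insulin signalling, fell 6.82-fold, the growth factor gene Igf2 4.87-fold and the cell cycle inhibitor gene Cdkn1c 4.02-fold. Tagln, a smooth muscle and fibroblast actin-binding protein, fell 4.15-fold, Ptch1, the hedgehog receptor, 3.78-fold, the transcription factor Sox11 3.71-fold and the surface protein gene Cd99 3.84-fold. Dhrs7 fell 4.35-fold and Rab26os at least 2.62-fold. In knockout cells, 2 of 3 arrays of Rab26os and 1 of 3 of Dhrs7 and Grb10 were at background. Eif2s3y on the Y chromosome had a signal of 379.3 ± 33.9 in wild-type cells and was at background in knockout cells, at least 2.98-fold lower. Probe sets of Mep1b, the semaphorin gene Sema3e, Skil, a repressor of SMAD signalling, and Zxda also fell to background, by at least 2.73-fold, 2.43-fold, 1.997-fold and 1.44-fold. Adjusted p-values by limma ran from 1.97e-06 for Igf2 to 0.0431 for Rab26os. The second probe set of Mep1b had the opposite sign (133.9 ± 135.4 and 211.5 ± 159.2, log2 difference 0.72, adjusted p = 0.708), and that of Ptch1 was not called (log2 difference -0.52, adjusted p = 0.226). A second probe set of Grb10 also fell (adjusted p = 0.00124), with 2 of 3 knockout arrays at background, and that of Sox11 fell at least 1.82-fold, while another of Grb10 and the second of Igf2 were at background in both groups. Zxda lost its call with each of the 6 arrays left out, Rab26os and Skil for 5, Dhrs7 and Sema3e for 4 and Mep1b for 2, with adjusted p up to 0.168.

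Pluripotency genes rose as a group. Of 28 measured, 11 were higher and 1 lower, and adjusted over the list alone 16 were higher and 1 lower, with a median log2 difference of 0.45 (camera adjusted p = 1.32e-10, and adjusted p = 0.0422 with an estimated correlation). Nanog, a core transcription factor of the pluripotent state, rose 2.11-fold from 5394.3 ± 196.7 to 11376.4 ± 471.6. Tfcp2l1 rose 2.36-fold, Zfp42, also called Rex1, 2.23-fold and Klf5 1.90-fold. The member that fell was Lefty1, an inhibitor of Nodal signalling, 2.03-fold lower. Pou5f1 (Oct4), chosen after its values were seen, had a log2 difference of 0.10 ± 0.09 with a signal of 10009.8 ± 1115 in wild-type and 10682.3 ± 380.7 in knockout cells (adjusted p = 0.706). When single arrays were left out, 8 to 10 members were higher and 1 lower. In the same arrays the feeder fibroblast markers were lower by a median of -0.41 (adjusted p = 0.0218 with an estimated correlation), and the 3' to 5' ratio of beta-actin was 1.19 in wild-type and 1.07 in knockout cells. X-linked genes were also higher in the knockout arrays, with a median log2 difference 0.388 above that of autosomal genes. No sample separates genotype from sex chromosomes, so the rise of the list cannot be assigned to HDAC1 alone.

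Imprinted genes, expressed from 1 parental copy, moved in both directions. Of 29 measured, 2 were higher, 5 lower and 22 without a call, and adjusted over the list alone 3 and 8, with a median of -0.14 (camera adjusted p = 0.0364, and adjusted p = 0.226 with an estimated correlation). Igf2, Cdkn1c and Phlda2, which lie in 1 imprinted region of chromosome 7, fell 4.87-fold, 4.02-fold and 2.35-fold. No other measured member of the list from that region was called, and the region itself was not tested as a list. Of the 32 listed imprinted genes 29 were measured, so nothing is said of members without a single-gene probe set. Grb10 on chromosome 11 fell, and of the 2 probe sets of Meg3 on chromosome 12, 1 rose. The other called members, chosen after their values were seen, were Peg3, 1.98-fold higher, and Gnas, 1.30-fold lower. In the same arrays the feeder fibroblast markers were lower (median -0.41, adjusted p = 0.0218 with an estimated correlation) and the beta-actin 3' to 5' ratio did not overlap between the genotypes. X-linked genes were higher in the knockout arrays, and no sample separates genotype from sex chromosomes. The list was no longer called without wild type replicate 3 (adjusted p = 0.177) or HDAC1 knockout replicate 1 (adjusted p = 0.0569), nor with array weights (adjusted p = 0.0646) or with the mean of all probe sets of a gene (adjusted p = 0.196). The same held without the dimmest 25% or 50% of probe sets (adjusted p = 0.0729 and 0.13), where its median was -0.07 and -0.03, and the median was -0.06 with median centring, -0.08 with quantile normalization and -0.23 without wild type replicate 2. Of the 7 cyclin-dependent kinase inhibitor genes, Cdkn1c was the 1 called, also adjusted over the list alone (camera adjusted p = 0.293). Cdkn1a, which encodes p21, had a signal of 1999.4 ± 286.8 in wild-type and 1950.0 ± 149.0 in knockout cells (log2 difference -0.03 ± 0.11, adjusted p = 0.95, of opposite sign at 0.05 after median centring). Its second probe set had 790.8 ± 28.4 and 638.3 ± 104.3, without overlap and without a call (log2 difference -0.32, adjusted p = 0.323), and Cdkn1b was at background in both.

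Actin cytoskeleton and adhesion genes fell as a group. Of 40 measured, 8 were lower and 0 higher by limma, and adjusted over the list alone 12 and 0, with a median of -0.27 (camera adjusted p = 7.05e-05, and adjusted p = 0.151 with an estimated correlation). The tropomyosin gene Tpm1 fell 1.84-fold, the annexin genes Anxa1 and Anxa2 1.76-fold and 1.59-fold, and the galectin gene Lgals1 1.42-fold. The feeder fibroblast marker list fell with them: 6 of 25 were lower and 0 higher, and adjusted over the list alone 7 and 0, with a median of -0.41 (camera adjusted p = 3.72e-06, and adjusted p = 0.0218 with an estimated correlation). Of the 25, 1 is also on the imprinted list (Dcn, chosen after its values were seen). Col1a1, a chain of type I collagen, fell 2.11-fold from 1010.5 ± 106.6 to 467.9 ± 17.5, S100a4 1.55-fold and Fbln2 1.40-fold, the last without a call when HDAC1 knockout replicate 2 was left out (adjusted p = 0.0627). With 1 array left out, 4 to 8 of the actin list and 4 to 5 of the fibroblast list were lower, and without HDAC1 knockout replicate 3 the median of the actin list was -0.13. The 3' to 5' ratio of beta-actin, 1.19 in wild-type and 1.07 in knockout arrays, did not overlap between the genotypes. For other abundant fibroblast genes, chosen after their values were seen, the log2 differences were 0.04 ± 0.16 for Col1a2, 0.05 ± 0.10 for Fn1 and -0.01 ± 0.13 for Col5a1, the last of opposite sign (0.07) after median centring. The interferon response and MHC class I list also went down, with a median of -0.31 (camera adjusted p = 0.0118, and adjusted p = 0.173 with an estimated correlation, and adjusted p = 0.0582 without wild type replicate 3), although B2m, the light chain of MHC class I and 2.18-fold lower, was the 1 member called of 28, also adjusted over the list alone. The next members by p were Psmb10 (log2 difference -0.48), H2-D1 (-0.29) and Ifitm3 (-0.18), none of them called by limma at adjusted p of 0.121, 0.269 and 0.272.

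Cholesterol and fatty acid synthesis genes were higher as a group, with 2 of 20 called higher, 7 adjusted over the list alone, and a median of 0.17 (camera adjusted p = 0.00248, and adjusted p = 0.157 with an estimated correlation). The sterol dehydrogenase gene Nsdhl, on the X chromosome, rose 2.11-fold and the desaturase gene Scd1 1.47-fold, while Fdft1 and Fdps had log2 differences of 0.43 and 0.31 (adjusted p = 0.053 and 0.0813). Scd1 lost its call for 4 of the 6 arrays left out, with adjusted p up to 0.1. The list's median was 0.025 without the X-linked and Y-linked genes, and 0.31 and 0.33 without the dimmest 25% and 50% of probe sets. S phase and mitosis genes went up by a median of 0.05, with 4 of 38 higher and 1 lower, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.0352, and adjusted p = 0.189 with an estimated correlation). Ccnd3 rose 1.76-fold, the ribonucleotide reductase subunit gene Rrm2 1.65-fold and the replication helicase gene Mcm4 1.27-fold, and Mycn fell 1.89-fold. With 1 array left out, 2 to 3 S phase genes were higher, and Mcm4 lost its call each time (adjusted p from 0.0596 to 0.111). The list's median was 0.12 with median centring, and 0.03, 0.11 and 0.08 without wild type replicate 1, wild type replicate 2 and HDAC1 knockout replicate 2. Oxidative phosphorylation genes had a median of 0.12 with 1 of 31 called, also adjusted over the list alone (camera adjusted p = 0.0459, and adjusted p = 0.495 with an estimated correlation). That member was Sdhd, a subunit of succinate dehydrogenase, 1.46-fold higher, followed by Uqcrc2, Uqcrb and Ndufc1 with log2 differences of 0.35, 0.29 and 0.22 and no call. The list's median was 0.05 without wild type replicate 3, 0.075 without the X-linked and Y-linked genes and 0.20 with median centring. The S phase and oxidative phosphorylation lists lost their camera call with quantile normalization (adjusted p = 0.125 and 0.126), and without wild type replicate 3 (adjusted p = 0.0582 and 0.362) or HDAC1 knockout replicate 1 (adjusted p = 0.0584 and 0.0779). The S phase list also lost it without wild type replicate 1 (adjusted p = 0.0797), and the oxidative phosphorylation list without HDAC1 knockout replicate 3 (adjusted p = 0.102) and without the X-linked and Y-linked genes (adjusted p = 0.0592). Without the dimmest 50% of probe sets neither was called (adjusted p = 0.103 and 0.117), and the oxidative phosphorylation list, which lost its call in 12 of 20 other settings, was not called without the dimmest 25% (adjusted p = 0.054), with array weights (adjusted p = 0.0952), with the mean of all probe sets (adjusted p = 0.0765) or by fry (adjusted p = 0.189).

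**Figure D2:**
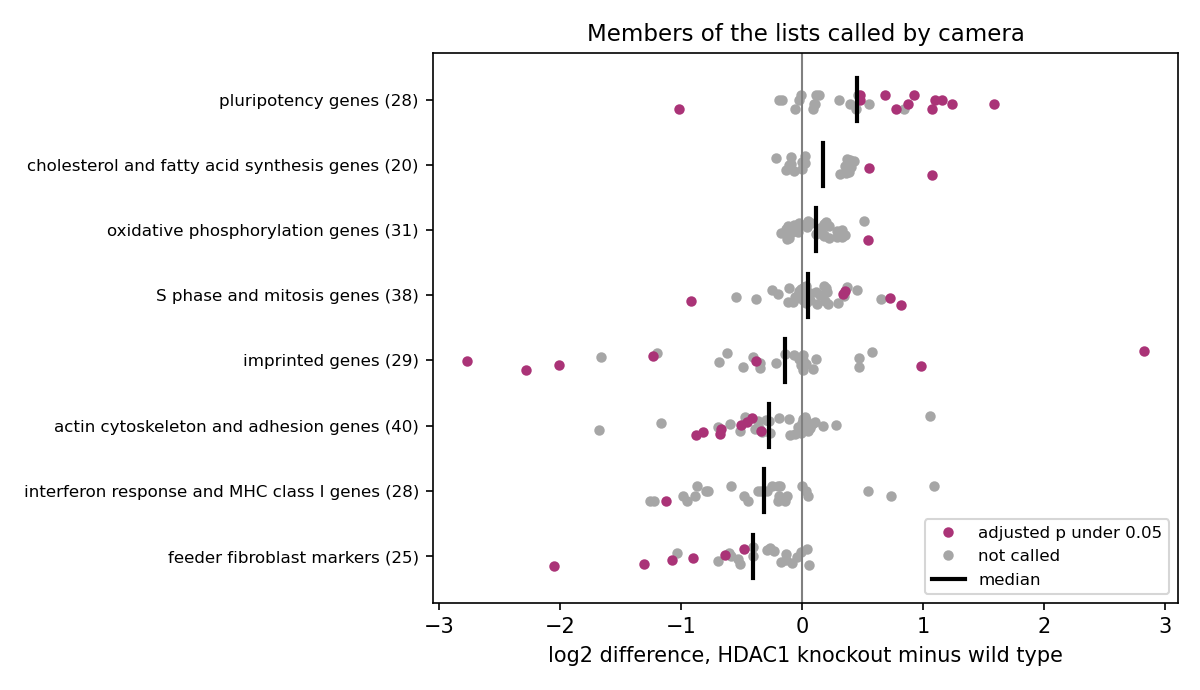
Log2 differences between HDAC1 knockout and wild-type cells (horizontal axis) of the members of the 7 gene lists and the 1 marker list called by camera, 1 point per gene, with the number of measured genes in parentheses. Purple points passed an adjusted p of 0.05 and black bars mark the medians, which run from -0.41 for fibroblast markers to 0.45 for pluripotency genes.

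Camera thus called 7 of 29 gene lists, 4 higher and 3 lower, against 1 with an estimated correlation and 15 by fry, which asks whether a list's genes move on balance in 1 direction and not whether they move more than other genes. For all of these lists, the same arrays had lower feeder fibroblast markers, a beta-actin 3' to 5' ratio without overlap between the genotypes, and higher X-linked genes. Leaving out wild type replicate 3 left 3 lists called, and leaving out HDAC1 knockout replicate 1 left 4. Among lists without a camera call, median, mean and test differed in sign for several. Camera's direction was up for neural genes (median -0.07, mean -0.15), histone genes (-0.03, -0.07), mesoderm genes (-0.02, 0.08), amino acid genes (-0.07, 0.01), methylation enzymes (0.07, -0.05) and histone deacetylases (0.01, -0.52), and down for Y-linked and Xist genes (0.47, -0.51).

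Among lineage genes, trophectoderm genes had 1 higher and 3 lower of 23, and 2 and 3 adjusted over the list alone (camera adjusted p = 0.685). The simple-epithelium keratin genes Krt18 and Krt8 fell 2.20-fold and 1.89-fold, Phlda2 fell, and Tfap2c rose 1.42-fold. In primitive and definitive endoderm genes, Lama1, a laminin chain, was the 1 called of 26 by both counts, over all probe sets and adjusted over the list alone, and rose 2.36-fold (camera adjusted p = 0.106). Bmp4 rose 2.01-fold as the 1 called of 25 mesoderm genes by both counts, also adjusted over the list alone (camera adjusted p = 0.617). Of 31 neural genes, 2 were higher, Stmn2 by 1.70-fold and Uchl1 by 1.33-fold, and 3 adjusted over the list alone (camera adjusted p = 0.77). Germline genes had 2 of 15 higher, 3 adjusted over the list alone, namely Rhox5 and the receptor gene Kit, 1.72-fold (camera adjusted p = 0.378). Uchl1 lost its call for 5 of the 6 arrays left out, and Tfap2c and Kit for 3, with adjusted p up to 0.137.

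Dnmt3a, a de novo DNA methyltransferase, fell 2.16-fold and the X-linked demethylase gene Kdm6a rose 1.78-fold among 15 methylation enzymes, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.757). Kat2b, an acetyltransferase, rose 1.48-fold as the 1 called of 10 acetyltransferases and sirtuins, 2 adjusted over the list alone (camera adjusted p = 0.13), and lost its call with each of the 6 arrays left out (adjusted p from 0.0525 to 0.121). In 20 genes known to respond to HDAC inhibitors, 3 were higher and 4 lower, and 4 and 5 adjusted over the list alone, without a shift of the list (camera adjusted p = 0.784). The metallothionein genes Mt1 and Mt2 rose 2.97-fold and 2.09-fold and the transcription factor gene Klf4 2.14-fold, while Krt18 fell 2.20-fold. H2ax rose 1.40-fold as the 1 called of 12 histone genes, also adjusted over the list alone (camera adjusted p = 0.757). Immediate early genes had 2 higher and 1 lower of 25, the same adjusted over the list alone (camera adjusted p = 0.771). Ccn2, a target of YAP and TGF-beta signalling, was 2.87-fold lower. The higher members were Klf4 and Klf2, the latter 1.84-fold, and both are also on the pluripotency list. Klf2 lost its call for 4 of the 6 arrays left out, with adjusted p up to 0.104.

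In signalling and metabolism, TGF-beta and BMP pathway genes had 2 higher and 4 lower of 35, the same adjusted over the list alone (camera adjusted p = 0.562), among them Nodal, 1.495-fold lower, and Id3, 1.57-fold lower. Nodal and Id3 lost their calls for 5 of the 6 arrays left out (adjusted p up to 0.124 and 0.105), and 1 to 2 members were then lower. Fzd2, a Wnt receptor, fell 2.53-fold as the 1 called of 30 Wnt pathway genes, also adjusted over the list alone (camera adjusted p = 0.685). Plk2 fell 1.66-fold as the 1 called of 14 p53 targets, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.106), and Mcl1, an inhibitor of apoptosis, 1.36-fold as the 1 of 27 apoptosis genes, 2 adjusted over the list alone (camera adjusted p = 0.328). Glycolysis and hypoxia genes had 2 higher and 2 lower of 27, and 4 and 3 adjusted over the list alone (camera adjusted p = 0.0861), with Pfkp 2.80-fold and the X-linked Pgk1 1.48-fold higher, and the glucose transporter gene Slc2a1 1.41-fold and Pdk1 1.44-fold lower. Slc2a1 lost its call with each of the 6 arrays left out (adjusted p from 0.065 to 0.127), Pdk1 for 5 (adjusted p up to 0.157) and Pgk1 for 2 (adjusted p up to 0.0567), and 0 to 1 members were lower by limma. Amino acid and one-carbon genes had 4 of 22 higher, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.46), namely Asns by 1.63-fold, Gldc, Mthfd2 and Odc1. With 1 array left out 1 to 2 were higher, since Mthfd2 and Odc1 lost their calls each time (adjusted p from 0.0521 to 0.143) and Gldc for 4 arrays (adjusted p up to 0.0794). Asns was also the 1 called of 25 heat shock and unfolded protein genes by both counts, also adjusted over the list alone (camera adjusted p = 0.705). Glutathione and antioxidant genes had 3 higher and 2 lower of 33, and 4 and 3 adjusted over the list alone (camera adjusted p = 0.509). Gpx2 was 1.86-fold higher and Hmox1 1.33-fold lower. The other higher members were Mt1 and Mt2, which are also on the list of genes that respond to HDAC inhibitors. Rpl13a fell 1.56-fold as the 1 called of 20 ribosomal protein genes, also adjusted over the list alone (camera adjusted p = 0.138). Hmox1 and Mcl1 lost their calls for 4 of the 6 arrays left out, and Gpx2, Rpl13a and Fzd2 for 2, with adjusted p up to 0.163.

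The called genes were spread unevenly over the chromosomes, a comparison made after the values had been seen. On the X chromosome 52 of 259 genes were higher (20.1%) and 6 lower, while 1.05% to 3.76% of genes on each autosome were higher. The median log2 difference of the 173 X-linked genes above background was 0.36, with 78.0% positive, and the autosomal medians ran from -0.08 to 0.01. Camera called the X chromosome higher among the chromosomes (adjusted p = 2.72e-10, and adjusted p = 0.0137 with an estimated correlation). Each knockout array, measured against the mean of the wild-type arrays, showed the shift, with X minus autosomal medians of 0.47, 0.38 and 0.38. Wild-type arrays, each measured against the mean of the other wild-type arrays, gave -0.05 to 0.03. These references use the genotype labels, so a two-sided permutation of the shifts is not an exact test. Its p was 0.1, the smallest that 3 against 3 arrays can give. X-linked genes made up 23.3% of the genes called higher and 3.1% of genes measured. Xist, the RNA that coats an inactive X chromosome, was at background in both genotypes. Among the other marker lists, 1 of 15 haematopoietic markers was called, also adjusted over the list alone (Laptm5, 2.09-fold higher, camera adjusted p = 0.47), none of 9 endothelial markers was by limma, with 2 higher adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.137), and Eif2s3y was the 1 of 5 Y-linked and Xist genes, also adjusted over the list alone (camera adjusted p = 0.511).

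**Figure D3:**
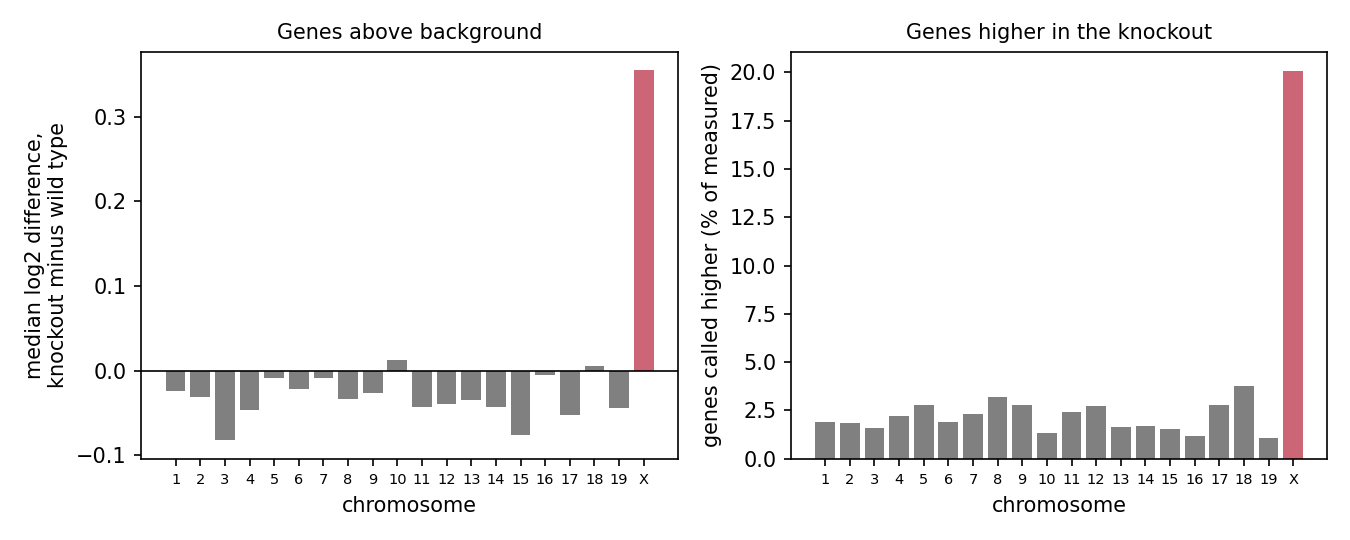
Left, the median log2 difference (HDAC1 knockout minus wild type) of genes above background on each chromosome. Right, the percent of measured genes called higher in knockout cells. The X chromosome (red) has a median of 0.36 and 20.1% of its genes higher, and the autosomes (grey) lie between -0.08 and 0.01 and between 1.05% and 3.76%.

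The 3' to 5' signal ratio of Gapdh was 0.802 ± 0.006 (SD, n = 3) in wild-type and 0.789 ± 0.018 in knockout arrays (exact two-sided permutation p = 0.4). That of beta-actin was 1.19 ± 0.033 and 1.07 ± 0.027, without overlap (exact two-sided permutation p = 0.1, the smallest this design allows).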

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

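The comparison of antisense controls was chosen after their values had been seen. Antisense control probe sets, which no comparison used, were brighter on 1 array than on the wild-type arrays. The median signal of the 15 antisense controls was 338.1 on HDAC1 knockout replicate 1, against 129.2 to 165.6 on the wild-type arrays and 149.4 and 114.1 on the other knockout arrays. That array was the highest of the 6 for 11 of the 15 controls, for example with a signal of 489.6 for the BioC control, where the others lay between 23.5 and 56.0. Without it, 183 probe sets were higher and 121 lower.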

How the results depend on the processing

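The fit without X-linked and Y-linked genes was chosen after the data had been seen. Hdac1 stayed lower and past the threshold under every setting run, with log2 differences from -4.16 to -3.55. Over 123 results for named genes, 1319 values under alternatives gave 103 lost calls, 10 gained calls and 3 changes of sign. With 1 array left out, 738 values gave 152, 2 and 10. Most of the 103 calls lost under alternatives were lost in the fit without a trend, with adjusted p up to 0.379 by limma (Atpif1). Among them were Hdac6, Dnmt3a, Lefty1, Krt8, Sox11, B2m, Tpm1 and Dusp6 (adjusted p from 0.0581 to 0.167 by limma). Klf5, Bmp4, Ccnd3, Rrm2, Anxa1, Anxa2, Lgals1, Hprt and Usp9x also lost their calls in that fit. So did the called neighbours of Hdac1 other than Laptm5. Nanog, Igf2 and Cdkn1c kept theirs in every setting run. None of the changes of sign was in a called gene. The medians of the called lists kept their sign under the alternatives and left-out arrays run, though not their size, as from 0.025 to 0.33 for cholesterol and fatty acid synthesis genes. Signal over background limits 39.2% of probe sets, whose mean was at or under the background level.

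With median centring, which moved the median of all probe sets by 0.08, 129 probe sets were lower. Without a trend 82 were higher and 50 lower, and 115 of the 482 calls were shared; the cause was not tested. At an adjusted p under 0.01 the counts were 153 and 84, and at 2-fold or more 92 and 66, by construction. With 1 array left out, and so from fewer samples, 150 to 246 were higher and 98 to 174 lower, and 3 to 8 lists were called. The estimated correlation left 1 list called and fry called 15, each by its own construction.

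With the replicate number as a block, 200 probe sets were higher and 119 lower, and 310 of the 482 calls were shared; the oxidative phosphorylation list lost its call (adjusted p = 0.0579). Across probe sets above background, the deviations of arrays with the same number correlated at -0.05, -0.01 and -0.08, so the numbers were not taken to pair samples. The block of scan or fluidics batches was not run because the experiment headers of the 6 arrays were identical. Whether such batches existed, and whether they followed genotype, is therefore unknown.

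The changes of sign were in genes without a call, and the cause was not tested. Cdkn1a had a log2 difference of 0.049 and Col5a1 of 0.068 with median centring, and Col5a1 of 0.002 with array weights. With 1 array left out, the log2 difference ran from -0.108 to 0.083 for Cdkn1a, from -0.092 to 0.071 for Col5a1, from -0.09 to 0.25 for Col1a2, from -0.032 to 0.126 for Fn1, from -0.13 to 0.20 for Spry4 and from -0.36 to 0.24 for Hdac3.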

Other observations

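The split of arrays by genotype and the 4 parts of the X chromosome were tested as stated before their results were seen, and the tests of scaling, of HDAC1 acting on the X chromosome, of feeder cells, of chance placement and of strain were chosen only after the result was seen. The genes named in this part were also chosen after their values were seen. Among single X-linked genes outside the lists described, Fmr1nb was 2.57-fold and Trap1a 1.995-fold higher in knockout cells. On autosomes, Tex19.1 rose 2.35-fold and Tcl1 2.26-fold. Of X-linked genes used in many cell types, Hprt, of purine salvage, was 1.44-fold, the deubiquitinase gene Usp9x 1.84-fold, Eif2s3x 1.42-fold and Huwe1 1.49-fold higher. Of other genes that the RefSeq table places on the X chromosome, Erdr1 fell 3.27-fold from 27013.1 to 8254.5 and Mid1 3.23-fold. Whether these genes also have copies on the Y chromosome was not examined, so their fall is not read as evidence on X-linked genes.

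Of 5 genes that feed back on ERK signalling, 2 were called. Dusp6 fell 2.16-fold from 1588.9 ± 118.3 to 732.9 ± 128.6 (SD over 3 arrays), and the X-linked Dusp9 rose 2.33-fold from 1914.8 ± 43.7 to 4481.8 ± 335.3. Spry4, Etv4 and Spred2 had log2 differences of 0.08 ± 0.20, 0.18 ± 0.15 and -0.32 ± 0.13 (SE) and no call.

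The split by genotype called 482 probe sets and the highest of the other splits called 0, so 1 of 10 splits gave as many. The splits of 6 arrays are too few for a share under 0.05.

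The X-linked genes above background were higher than the autosomal ones by a median of 0.388 on the log2 scale, a 1.31-fold difference. The tables argue against scaling between arrays as the whole cause, since a factor per array moves all chromosomes alike, the single autosomes had medians from -0.08 to 0.01, and the difference was 0.404 after quantile normalization. More active X chromosome per cell in the knockout cultures may account for it: each of 4 equal parts of the X-linked genes in gene order had a median above that of every autosome, the lowest being 0.332 against 0.013. Any shift spread along the chromosome would pass this test, whatever its cause, and the number of X chromosomes was not measured. The fall of Eif2s3y to background in knockout cells bears on the sex chromosomes of the cultures, but it is 1 gene and no karyotype is given. The Y-linked Kdm5d, Sry and Uba1y were at background in both genotypes and cannot tell. Uty had no call (adjusted p = 0.356 by limma) and cannot tell either. Its mean signals, 91.5 in wild-type and 35.4 in knockout cells, were both under the background level. Xist, at background in both, does not separate the genotypes. Loss of HDAC1 acting on X-linked genes, 78.0% of which had a positive difference, cannot be told apart from more active X chromosome per cell. The sex chromosomes of the samples are not given, and no sample separates them from genotype.

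Of the fibroblast markers 6 of 25 and of the actin and adhesion genes 8 of 40 were lower in knockout cells (camera adjusted p = 0.0218 and 0.151 with an estimated correlation), while the abundant Col1a2, Fn1 and Col5a1 had log2 differences of 0.04, 0.05 and -0.01, whose signs turned with single arrays left out. A smaller share of feeder fibroblasts in the knockout cultures is a candidate explanation, which needs the abundant fibroblast transcripts to fall together. Of 11 abundant markers other than Col1a1, 8 had intervals that exclude a fall as large as that of Col1a1 (2.11-fold), and the median log2 difference of all 12 abundant markers was -0.44. How much of these transcripts the stem cells make themselves is unknown, and feeders are not stated per sample, so this stays open. A change of the stem cells themselves was not tested separately.

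Among the 40 genes nearest to Hdac1 on chromosome 4, 20 on each side in gene order, 6 were called: Marcksl1, Fabp3, Snrnp40, Laptm5 and Gjb5 higher and Atpif1 lower, but 4 without wild type replicate 2 or 3 and 3 without each of the other arrays in turn. Of all such windows of autosomal genes, 0.666% held as many calls, but with 10 neighbours a side it was 4.48% and with 40 a side 10.1%, so chance placement stays open. DNA of another strain left around the targeted locus might also account for it. The share called was 15.0% among the nearest 40 genes and 6.2% among the next 80. Fisher's exact two-sided test did not separate these shares (p = 0.177), and no strain is compared within a genotype. In the fit without a trend, Laptm5 alone of the 6 called neighbours kept its call.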
